A study of Rattus norvegicus with 39 samples.

How the data were processed

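Total RNA from the left lateral lobe of the liver of rats 5 to 6 weeks old was hybridized as biotin-labelled cRNA to Affymetrix Rat 230 2.0 arrays, 1 array per animal, 48 h after a single treatment. The 39 arrays form 7 groups per the labels. The 6 compound groups hold 5 rats each and the untreated control group holds 9. The compounds were ANIT (alpha-naphthylisothiocyanate, 125 mg/kg in corn oil by mouth), Caerulein (50 µg/kg in saline by intraperitoneal injection), DMN (dimethylnitrosamine, 15 mg/kg in water by mouth), DNP (2,4-dinitrophenol, 15 mg/kg in water by mouth), NMF (N-methylformamide, 1000 mg/kg in saline by intraperitoneal injection) and Roziglitazone, as the labels spell rosiglitazone (1000 mg/kg in methylcellulose by mouth). The controls received no vehicle, so compound, vehicle and route were compared together. ANIT, DMN and NMF were taken as liver toxicants and the other 3 as compounds with other main targets, from what is known of the compounds and not from the labels.

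The values deposited by the authors are probe set intensities on a linear scale, from 5.4 to 23152.1, and the log2 was taken here. The submitters' notes name RMA and the affy package with no version, and RMA usually ends on a log2 scale, and the notes state no step that leads back to a linear scale. The plan made before the data were examined had assumed log2 values on deposit; the log2 step was added once the scale was seen. The mean intensity per array ran from 348 to 363 and the median from 77.8 to 109, so the arrays shared a scale without having identical distributions. No read depth exists for arrays; the number of arrays per group limits the precision.

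Of the 31099 probe sets, the 57 control probe sets served only to judge the arrays. The platform annotation gave 1 gene symbol to 20826 probe sets, several to 436 and none to 9780. Symbols were brought up to date through a rat gene table for 20758 probe sets and kept as they were for the 68 whose gene was not in that table. The table served for names alone, so no positions are given. Probe sets with several symbols were left out because their signal cannot be assigned, and those with none because they name no gene; the latter were fitted apart. For the 4525 genes with more than 1 probe set, the probe set with the highest mean over all 39 arrays stood for the gene, which left 14217 genes. No filter on dim genes was applied.

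A linear model with 1 mean per group was fitted to all 39 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes with default settings) in R 4.3.3. Each compound was compared with the controls, ANIT, DMN and NMF with each other in pairs, and the mean of the 3 toxicants with the mean of the other 3 compounds. P values were adjusted by Benjamini and Hochberg over the 14217 genes of a contrast, and a gene was called at an adjusted p under 0.05. Each fold change is given with its SE from limma and group levels as mean log2 intensity with the SD. A fold against a group mean inside the range of the poly-A spikes, 3.47 to 4.80, is near background and is given as a lower bound. Genes whose arrays do not overlap between the groups were counted beside the number that chance gives. Genes called the same way in ANIT, DMN and NMF were counted against what independence and 3 separate control arrays per compound give, because the compounds share their controls. Correlations of fold changes were set against 100 simulations with no planted effect, drawn from the deviations of all 39 arrays from their group means.

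The 33 gene lists were written before the data were examined and had at least 5 measured members each. They cover bile acid synthesis, hepatocyte uptake and canalicular transporters, basolateral efflux and multidrug transporters, p53 targets, NRF2 targets, cell cycle, extracellular matrix and stellate cell, macrophage, neutrophil, lymphocyte, cholangiocyte, endothelial, erythroid and pancreatic acinar cells, hepatocyte function, pericentral and periportal hepatocytes, acute phase, chemokines and inflammatory signals, interferon response, apoptosis and cell death regulators, endoplasmic reticulum stress, heat shock, PPARA targets and fatty acid oxidation, PPARG targets and adipocyte, lipogenesis, cholesterol synthesis, xenobiotic cytochromes P450, conjugation enzymes, oxidative phosphorylation, gluconeogenesis and fasting, circadian clock, and growth hormone dependent genes. Some genes stand on several lists. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, on 7 contrasts, and the 231 tests were adjusted together. The same tests were run with a correlation estimated from the data, and with fry, which asks whether a list moves on balance and does not compare it with other genes. The pairwise contrasts of the toxicants have counts of members only.

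Genes were named by a rule fixed before the data were examined. It took, per contrast, the 10 genes per direction with the largest fold change among called genes whose arrays do not overlap (for the class contrast, whose compound means do not overlap). It added up to 4 members of a list past the threshold and up to 2 not past it, with the largest changes, and for the genes called in all 3 toxicants the 10 per direction with the largest smallest change.

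The pipeline was tested on simulated data: 20 simulations, each with 200 changed genes and 1 changed list planted in ANIT. It recovered 32.4% of genes changed 1.5-fold, 77.2% of those changed 2-fold, 96.1% at 3-fold and 98.5% at 4-fold, and 5.38% of its calls were false. It made 1 call over all simulations in a contrast with nothing planted. The planted list was called in 20 of 20 simulations, and 0.0223% of tests of other lists were called. That rate holds for the simulated data and was not shown for the real arrays. On drawn splits of the real arrays, the median number of lists called was 8 for ANIT, 4 for Caerulein and 9 for DMN. It was 5 for DNP, 8 for NMF and 6 for Roziglitazone.

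Alternatives planned before the data were examined were the mean of a gene's probe sets, all probe sets, leaving out the 30% or 50% of genes with the lowest means, a further quantile normalization, centring each array on its median, limma with a trended and robust prior, array weights, a fit to the named groups only, a per-gene test with unequal variances, the replicate number as a block, other list tests, split controls, leaving out each other compound from the class contrast, and leaving out each array. Added after the data were seen were fits without the 3 arrays labelled ANIT 3, DMN 2 and Roziglitazone 2, without 6 arrays low in GAPDH 5′ signal, without both sets, and with the 6 arrays as a block. No array was left out of the values reported first. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.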

Results

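Expression was measured on 39 arrays, 1 per rat liver, taken 48 h after a single treatment. The 6 compound groups (ANIT, Caerulein, DMN, DNP, NMF and Roziglitazone) had 5 rats each and the untreated control group had 9. Values are log2 intensities of 14217 genes, and the number of arrays limits the precision. The controls received no vehicle, so each comparison with them takes compound, vehicle and route together. The labels of 3 arrays were in doubt. The deviation of each array from the mean of all other arrays was correlated across genes with the deviation of each group mean from it, the array itself left out; the intensities themselves correlated at 0.855 to 0.992 over all pairs of arrays. The deviation of the array labelled ANIT 3 correlated at 0.705 with that of DMN and 0.301 with that of the other ANIT arrays, and that of Roziglitazone 2 at 0.802 with ANIT and −0.303 with its own group. For the array labelled DMN 2 the deviation correlated with that of no group above 0.120, and with that of the other DMN arrays at 0.00344. This measure alone did not single out the doubted arrays, since 15 of 39 arrays correlated best with their own group. Roziglitazone 1 (−0.221), control 5 (−0.0860) and DNP 1 (−0.0612) correlated less with their own groups than DMN 2 did. The group means kept the other doubted arrays, so the Roziglitazone mean set against DMN 2 held the array labelled Roziglitazone 2. All 3 doubted arrays were kept, and counts without them, a choice made after the data were seen, stand beside the main counts. Whether the numbers 1 to 5 within groups pair the samples was not settled, and the main fit did not use them. In 1 of 21 pairs of groups all 5 same-numbered pairs of arrays correlated above 0.1 in their deviations from the group means. Of 105 same-numbered pairs 58 did so, and no such count was made for unlike-numbered pairs.

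The liver 48 h after ANIT, which injures the cells of the bile ducts and stops bile flow, was compared with untreated liver. Lcn2, which encodes an iron-binding protein of the acute phase, rose from 8.01 ± 0.96 (SD, n = 9) to 12.93 ± 0.30 (SD, n = 5), a 30.2-fold change (log2 fold change 4.92 ± 0.90 SE, adjusted p = 2.07e-04). Abcc3, whose product moves bile acid conjugates back into the blood, rose 19.7-fold (4.30 ± 0.70, adjusted p = 4.97e-05), and Abcb4, the exporter of phospholipid into bile, rose 3.99-fold (2.00 ± 0.30, adjusted p = 2.05e-05). Abcc3 was at 7.15 in the array labelled ANIT 3 and at 10.10 to 11.21 in the other ANIT arrays. The sterol exporters Abcg5 and Abcg8 fell 3.91-fold and 2.90-fold, calls that were lost with the replicate number as a block. The largest fall was that of Stac3, which encodes an adaptor protein best known from muscle, from 10.83 ± 0.41 to 5.52 ± 0.40, or 39.6-fold (−5.31 ± 0.62, adjusted p = 7.91e-07). Each of these genes moved the same way in all 5 ANIT arrays. For the 10 largest changes per direction in each comparison with control or between toxicants this was fixed by choosing genes whose arrays do not overlap; of the 29 genes named for this contrast without that condition, 23 did so.

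In limma, 2344 genes were called in ANIT, 1165 higher and 1179 lower, and 566 of them changed at least 2-fold. The 5 ANIT arrays and 9 control arrays did not overlap in 816 genes, 766 of them called, where chance gives 14.2. Without the arrays labelled ANIT 3, DMN 2 and Roziglitazone 2 there were 2270 calls, of which 1943 were among the 2344. Array weights raised the count to 4839, and leaving out 6 arrays low in GAPDH 5′ signal raised it to 3632. The balance of directions depended on scaling: with each array centred on its median, 1666 genes were higher and 627 lower, and with quantile normalization once more 1073 and 1009. Among the other largest rises were the GTPase gene Rnd1 (18.2-fold), the transcription factor gene Mybl1 (at least 15.6-fold, the control mean of 4.06 being near background), the glutathione peroxidase gene Gpx2 (10.3-fold), the protease inhibitor gene A2m (10.2-fold) and the ubiquitin ligase gene Neurl3 (9.77-fold). Among the largest falls were Serpina6, which encodes the corticosteroid carrier of plasma (17.1-fold), Gstp3 (15.0-fold), the carbonic anhydrase gene Car3 (14.4-fold), the pyruvate kinase gene Pklr (9.31-fold) and Oat, which encodes ornithine aminotransferase (6.65-fold).

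Growth hormone dependent genes fell in ANIT. Of 17 measured, 14 were lower and none higher (14 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of −1.22 and a camera adjusted p of 1.14e-09; adjusted p = 0.0600 with an estimated correlation. Besides Serpina6, the male-pattern cytochrome Cyp2c11 fell 6.49-fold, the urinary protein gene Obp3 4.10-fold and Cyp3a2 3.75-fold. The same list had adjusted p = 0.00195 with an estimated correlation without the 3 doubted arrays.

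Cholesterol synthesis rose in ANIT, with 10 of 22 genes higher and none lower (13 and 1 adjusted over the list alone), a median of 0.73 and a camera adjusted p of 2.05e-07; adjusted p = 0.323 with an estimated correlation. Idi1, which makes the isoprenoid building block, rose 5.13-fold, the epoxidase gene Sqle 3.93-fold, Mvd 3.77-fold and Acat2 3.49-fold. The array labelled ANIT 3 stood apart here: its mean level over the list was −0.60 against the controls, while the other 4 ANIT arrays lay from 1.05 to 1.47. Idi1, Mvd and Acat2 were accordingly above the control mean in 4 of 5 ANIT arrays. Cholesterol synthesis had adjusted p = 0.0207 with an estimated correlation once the 3 doubted arrays were left out.

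Further lists passed the camera threshold in ANIT, 17 in all. Cell cycle genes had 11 of 37 higher (15 adjusted over the list alone, median 0.42, camera adjusted p = 4.27e-06; adjusted p = 0.441 with an estimated correlation), led by the replication gene Mcm6 (4.75-fold) and the cyclin gene Ccnd1 (4.50-fold). In the array labelled ANIT 3 the mean level of this list was 1.54 and in the other 4 it was 0.16 to 0.40. The cyclin gene Ccna2, near background in the controls at 4.33, rose at least 3.65-fold (adjusted p = 0.0248), a call lost without that array (adjusted p = 0.151). Acute phase genes had 7 of 24 higher and 1 lower (10 and 2 adjusted over the list alone, camera adjusted p = 2.8e-04; adjusted p = 0.399 with an estimated correlation), among them Lcn2, A2m and the lipopolysaccharide-binding protein gene Lbp (4.56-fold). NRF2 targets had 6 of 23 higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.00109; adjusted p = 0.200 with an estimated correlation), among them Srxn1 (6.24-fold) and the heme oxygenase gene Hmox1 (3.58-fold). Heat shock genes had 5 of 15 higher and none lower (7 higher adjusted over the list alone, camera adjusted p = 1.72e-05; adjusted p = 0.142 with an estimated correlation), with the small chaperone gene Cryab at 3.07-fold.

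Xenobiotic cytochromes P450 had 11 of 28 lower and 3 higher in ANIT (12 and 3 adjusted over the list alone, camera adjusted p = 0.00258; adjusted p = 0.357 with an estimated correlation), Cyp1a1 being higher by 10.7-fold in 4 of 5 arrays. Periportal hepatocyte genes had 7 of 14 lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.266 with an estimated correlation), and pancreatic acinar genes 5 of 13 lower (adjusted p = 0.411 with an estimated correlation). Lymphocyte genes had 4 of 20 lower (adjusted p = 0.520 with an estimated correlation). Their camera call was lost with the replicate number as a block (adjusted p = 0.0816) and without the 30% of genes with the lowest means (0.107). The camera calls of 4 lists were lost without the array labelled ANIT 3: p53 targets (6 of 19 higher, 1 lower, adjusted p = 0.0967 without it), apoptosis and cell death regulators (10 of 37 higher, 1 lower; 0.0539), lipogenesis (5 of 21 lower, 1 higher; 0.0977) and pericentral hepatocytes (3 of 14 lower; 0.124). The pericentral call was also lost without control 1, 3, 6, 7 or 8 (adjusted p from 0.0509 to 0.0649). The chemokine list (8 of 28 higher, 1 lower) lost its call without ANIT 5 (adjusted p = 0.202) or control 1, 5 or 8 (0.0509 to 0.0631). Oxidative phosphorylation (4 of 24 lower) lost it without ANIT 5 (0.308) or control 4 (0.0510), and basolateral efflux transporters (3 of 6 higher) without control 5 (0.0556). With an estimated correlation these 7 lists had adjusted p from 0.133 to 0.613. Adjusted over the list alone, their higher and lower members were 6 and 2 for p53 targets, 10 and 3 for cell death regulators, 1 and 7 for lipogenesis, 1 and 4 for pericentral genes, and as before for the other 3. In the fit with all arrays, the array labelled ANIT 3 included, Phlda3 and Ccng1 among the p53 targets were at 2.78-fold and 2.97-fold. Among the cell death genes the cytokine receptor gene Tnfrsf12a was at 7.73-fold.

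**Figure D1:**
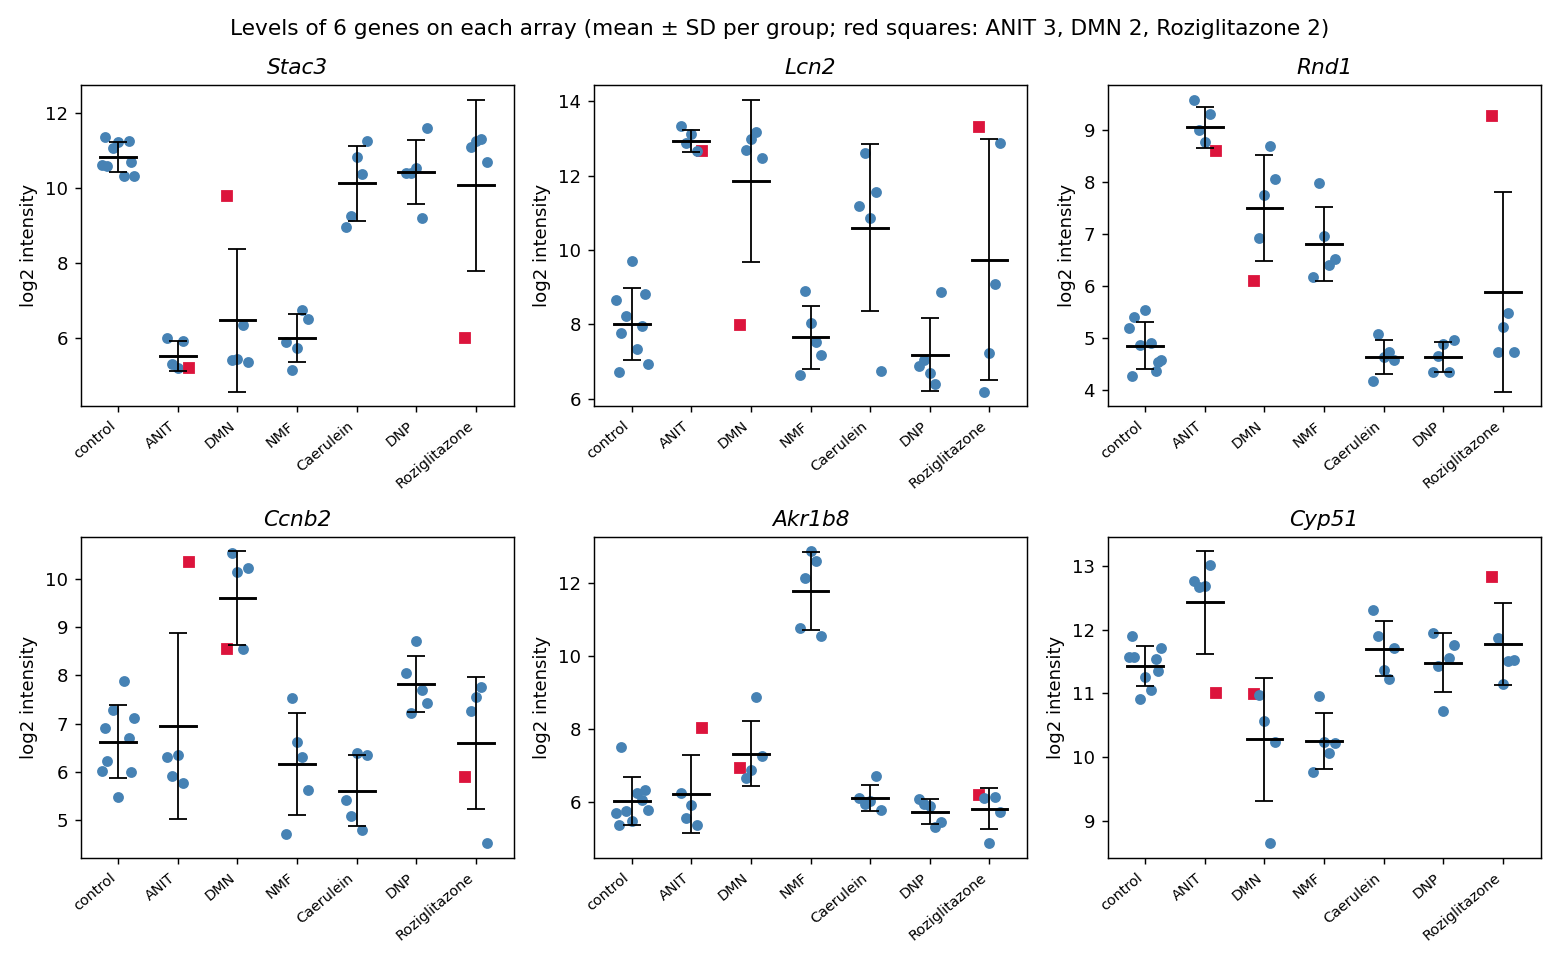
Log2 intensity of Stac3, Lcn2, Rnd1, Ccnb2, Akr1b8 and Cyp51 on each of the 39 arrays by group, with the group mean and SD; red squares are the arrays labelled ANIT 3, DMN 2 and Roziglitazone 2. Stac3 is at 5.52 ± 0.40 in ANIT and 10.83 ± 0.41 in the controls, and Akr1b8 is at 11.79 ± 1.07 in NMF and 6.03 ± 0.65 in the controls.

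DMN, a nitrosamine that alkylates DNA and damages the liver around the central veins, was compared with untreated liver. Cell cycle genes rose: the cyclin gene Ccna2, near background in the controls, by at least 10.9-fold (3.45 ± 0.59, adjusted p = 1.45e-04), Ube2c, which helps degrade cyclins, by 8.06-fold (3.01 ± 0.46, adjusted p = 3.82e-05), Ccnb2 by 7.83-fold and the kinase gene Cdk1 by 6.12-fold. The p53 targets Ccng1, Mdm2 and Phlda3 rose 4.68-fold, 3.17-fold and 3.07-fold (Mdm2 1.66 ± 0.26, adjusted p = 4.26e-05). Adam8, a surface protease of white blood cells, rose from 5.70 ± 0.48 (SD, n = 9) to 9.61 ± 0.68 (SD, n = 5), or 15.1-fold (3.91 ± 0.46, adjusted p = 1.51e-06). All 5 DMN arrays lay on the called side of the control mean for each of these genes, and for 19 of the 24 named for this contrast without the condition on overlap.

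In limma, 1478 genes were called in DMN, 834 higher and 644 lower, 432 of them by at least 2-fold. The arrays of the 2 groups did not overlap in 331 genes, 311 of them called, where chance gives 14.2. Without the 3 doubted arrays there were 1970 calls, 1368 of them shared with the 1478. Array weights raised the count to 3468, a fit to the DMN and control arrays alone gave 859, and the per-gene test with unequal variances 219. With each array centred on its median 1047 genes were higher and 339 lower. Further large rises were those of the laminin gene Lama5 (11.7-fold), the fatty acid binding protein gene Fabp4 (log2 3.33 ± 0.47), the macrophage glycoprotein gene Gpnmb (9.28-fold) and Kif20b, which acts in cell division (at least 9.24-fold, the control mean of 3.87 being near background). Stac3 fell 20.5-fold, Inmt 6.17-fold, Sez6 5.66-fold, Oat 4.90-fold and Scd, which desaturates fatty acids, 4.01-fold. Stac3 was at 9.79 in the array labelled DMN 2 and at 5.38 to 6.34 in the other DMN arrays.

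Cell cycle had the lowest camera adjusted p of the 33 lists in DMN, with 27 of 37 genes higher and none lower (31 higher adjusted over the list alone), a median of 0.98, an adjusted p of 3.92e-27 and adjusted p = 0.0287 with an estimated correlation. The array labelled DMN 2 had a mean level of 0.43 over this list and the other 4 DMN arrays 0.90 to 1.72. p53 targets had 10 of 19 higher and 1 lower (10 and 3 adjusted over the list alone, median 0.65, camera adjusted p = 3.14e-06; adjusted p = 0.0117 with an estimated correlation). Pericentral hepatocyte genes had 5 of 14 lower (7 adjusted over the list alone, median −0.62, camera adjusted p = 9.08e-06; adjusted p = 0.0445 with an estimated correlation), led by Slc13a3, a carrier of dicarboxylates (4.93-fold), and Oat.

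Lipogenesis fell in DMN, with 12 of 21 lower (14 adjusted over the list alone, median −1.11, camera adjusted p = 2.59e-09; adjusted p = 0.0735 with an estimated correlation). Besides Scd, Pklr fell 4.00-fold, the acetate-activating Acss2 3.91-fold and the citrate lyase gene Acly 3.08-fold. Growth hormone dependent genes had 9 of 17 lower (11 adjusted over the list alone, median −0.74, camera adjusted p = 1.64e-08; adjusted p = 0.0735 with an estimated correlation), with Cyp2c11 down 4.01-fold and Igfals, a carrier of insulin-like growth factors, 3.16-fold. Xenobiotic cytochromes P450 had 9 of 28 lower (11 adjusted over the list alone, adjusted p = 0.0735 with an estimated correlation), Cyp2j3 by 2.90-fold. In the array labelled DMN 2 the growth hormone dependent list lay at −0.14, against −0.84 to −1.75 in the others, and Lcn2, which rose 14.5-fold in the group, was near the control mean of 8.01.

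Cholesterol synthesis had 7 of 22 lower in DMN (10 lower and 1 higher adjusted over the list alone, median −0.64; adjusted p = 0.520 with an estimated correlation). Endoplasmic reticulum stress had 5 of 23 higher (9 adjusted over the list alone, adjusted p = 0.236 with an estimated correlation), with Ddit3 up 3.03-fold, and apoptosis and cell death regulators had 8 of 37 higher (adjusted p = 0.0718 with an estimated correlation), with the death receptor gene Fas up 2.49-fold and Apaf1 1.97-fold. Several of the 16 camera calls rested on 1 array. Endothelial genes (4 of 12 lower; Stab2 by 4.23-fold, Kdr by 3.09-fold) lost theirs without DMN 1 or 3 or control 3 or 4 (adjusted p from 0.0538 to 0.0681). Without DMN 5, the calls of bile acid synthesis (5 of 13 lower, adjusted p = 0.0563), neutrophils (5 of 13 higher, 1 lower; 0.0923), macrophages (5 of 17 higher, 1 lower; 0.149) and periportal hepatocytes (3 of 14 lower; 0.190) were lost. Without control 5, those of macrophages (0.0913) and acute phase (4 of 24 higher, 1 lower; 0.0619) were lost, and without DMN 3 that of heat shock (2 of 15 higher; 0.102). With an estimated correlation these 7 lists had adjusted p from 0.215 to 0.520. Adjusted over the list alone, bile acid synthesis had 7 lower, neutrophils 6 higher and 1 lower, macrophages 5 and 2, periportal genes 4 lower, acute phase 5 higher and 1 lower, and endothelial and heat shock genes the same counts as over all genes. Single members stood out, with the neutrophil gene S100a8 up 4.51-fold in 4 of 5 arrays (2.17 ± 0.45, adjusted p = 0.00122) and the lysozyme gene Lyz2 up 3.49-fold (1.80 ± 0.24, adjusted p = 5.3e-06).

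NMF, a formamide whose metabolites deplete glutathione, was compared with untreated liver. Akr1b8, which encodes an aldose reductase, rose from 6.03 ± 0.65 (SD, n = 9) to 11.79 ± 1.07 (SD, n = 5), or 54.2-fold (5.76 ± 0.39, adjusted p = 3.59e-13). The glutathione enzyme genes Gpx2, Gsta3 and Gstp1 rose 19.9-fold, 16.8-fold and 13.1-fold (Gstp1 3.71 ± 0.27, adjusted p = 1.54e-12), and Abcc3 rose 26.3-fold. Scd fell from 12.67 ± 0.47 to 8.07 ± 0.34, or 24.4-fold (−4.61 ± 0.33, adjusted p = 1.01e-12), and Cyp1a2 fell 7.76-fold (−2.96 ± 0.13, adjusted p = 7.28e-19). Each held in all 5 NMF arrays, as did 19 of the 20 genes named for this contrast without the condition on overlap.

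In limma, 1063 genes were called in NMF, 547 higher and 516 lower, 287 of them by at least 2-fold. The arrays did not overlap in 560 genes, 499 of them called, where chance gives 14.2. Without the 3 doubted arrays, none of them an NMF array, 1206 genes were called, 1050 of them among the 1063. Array weights raised the count to 1900, and leaving out these 3 arrays together with the 6 low in GAPDH 5′ signal raised it to 1633. With each array centred on its median 736 genes were higher and 308 lower. Other large rises were those of Akr7a3, an aflatoxin aldehyde reductase (9.75-fold), and Gpnmb (5.08-fold). Other large falls were those of Stac3 (28.3-fold), the flavin monooxygenase gene Fmo1 (25.4-fold), Nrep (23.8-fold), Akr1c1 (15.9-fold) and Rgn, which encodes regucalcin (8.84-fold).

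NRF2 targets rose in NMF, with 14 of 23 higher and 1 lower (17 and 1 adjusted over the list alone), a median of 0.86, a camera adjusted p of 6.24e-22 and adjusted p = 2.3e-04 with an estimated correlation. PPARA targets had 9 of 31 higher (11 adjusted over the list alone, median 0.33, camera adjusted p = 2.32e-05; adjusted p = 0.0445 with an estimated correlation), with the thioesterase genes Acot4 and Acot2 up 3.24-fold and 2.55-fold. Lipogenesis had 14 of 21 lower (16 adjusted over the list alone, median −1.33, camera adjusted p = 3.08e-14; adjusted p = 0.0242 with an estimated correlation), with Pklr down 7.56-fold, Fads2 4.11-fold and Fasn 4.04-fold. Growth hormone dependent genes had 13 of 17 lower (15 lower and 1 higher adjusted over the list alone, median −1.15; adjusted p = 0.0242 with an estimated correlation), among them Serpina6 (5.57-fold) and Cyp2c13 (4.52-fold). Pericentral genes had 6 of 14 lower and 1 higher (8 and 1 adjusted over the list alone, median −0.79; adjusted p = 0.0101 with an estimated correlation), among them Rgn, Cyp1a2 and Slc13a3 (8.70-fold). Xenobiotic cytochromes P450 had 13 of 28 lower (15 lower and 3 higher adjusted over the list alone, median −0.55; adjusted p = 0.0287 with an estimated correlation).

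Other lists passed the camera threshold in NMF but not with an estimated correlation. Extracellular matrix and stellate cell genes had 8 of 26 lower (11 adjusted over the list alone, adjusted p = 0.0735 with an estimated correlation), with the collagen gene Col1a1 down 2.63-fold and the retinol acyltransferase gene Lrat 3.45-fold. Endoplasmic reticulum stress had 6 of 23 higher (8 adjusted over the list alone, adjusted p = 0.0548 with an estimated correlation), led by the asparagine synthetase gene Asns (4.53-fold). Conjugation enzymes had 9 of 28 higher and 3 lower (11 and 4 adjusted over the list alone, adjusted p = 0.0935 with an estimated correlation). Basolateral efflux transporters had 3 of 6 higher (adjusted p = 0.0973 with an estimated correlation), heat shock 5 of 15 higher (0.133) and cholesterol synthesis 4 of 22 lower (11 adjusted over the list alone; 0.436). Endothelial genes passed at list level with no member called over all genes (2 lower adjusted over the list alone; 0.411). The calls of 3 lists were lost without any 1 of several arrays. Macrophages (4 of 17 lower, 1 higher) lost it without NMF 1, 2, 3 or 5 or control 6 or 7 (adjusted p from 0.0511 to 0.121). Lymphocytes (none called) lost it without NMF 3 or 4 or control 2, 3, 6, 7 or 9 (0.0554 to 0.231), and periportal hepatocytes (3 of 14 lower) without NMF 2, 3 or 5 or control 3, 5, 6, 7 or 8 (0.0540 to 0.0750). In bile acid handling, Cyp7a1, which starts bile acid synthesis, fell 6.44-fold (−2.69 ± 0.68, adjusted p = 0.00917), and the uptake carrier gene Slco1a4 fell too (−2.14 ± 0.28, adjusted p = 1.29e-06), while the bile acid synthesis list as a whole (3 of 13 lower, camera adjusted p = 0.0538) did not pass.

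**Figure D2:**
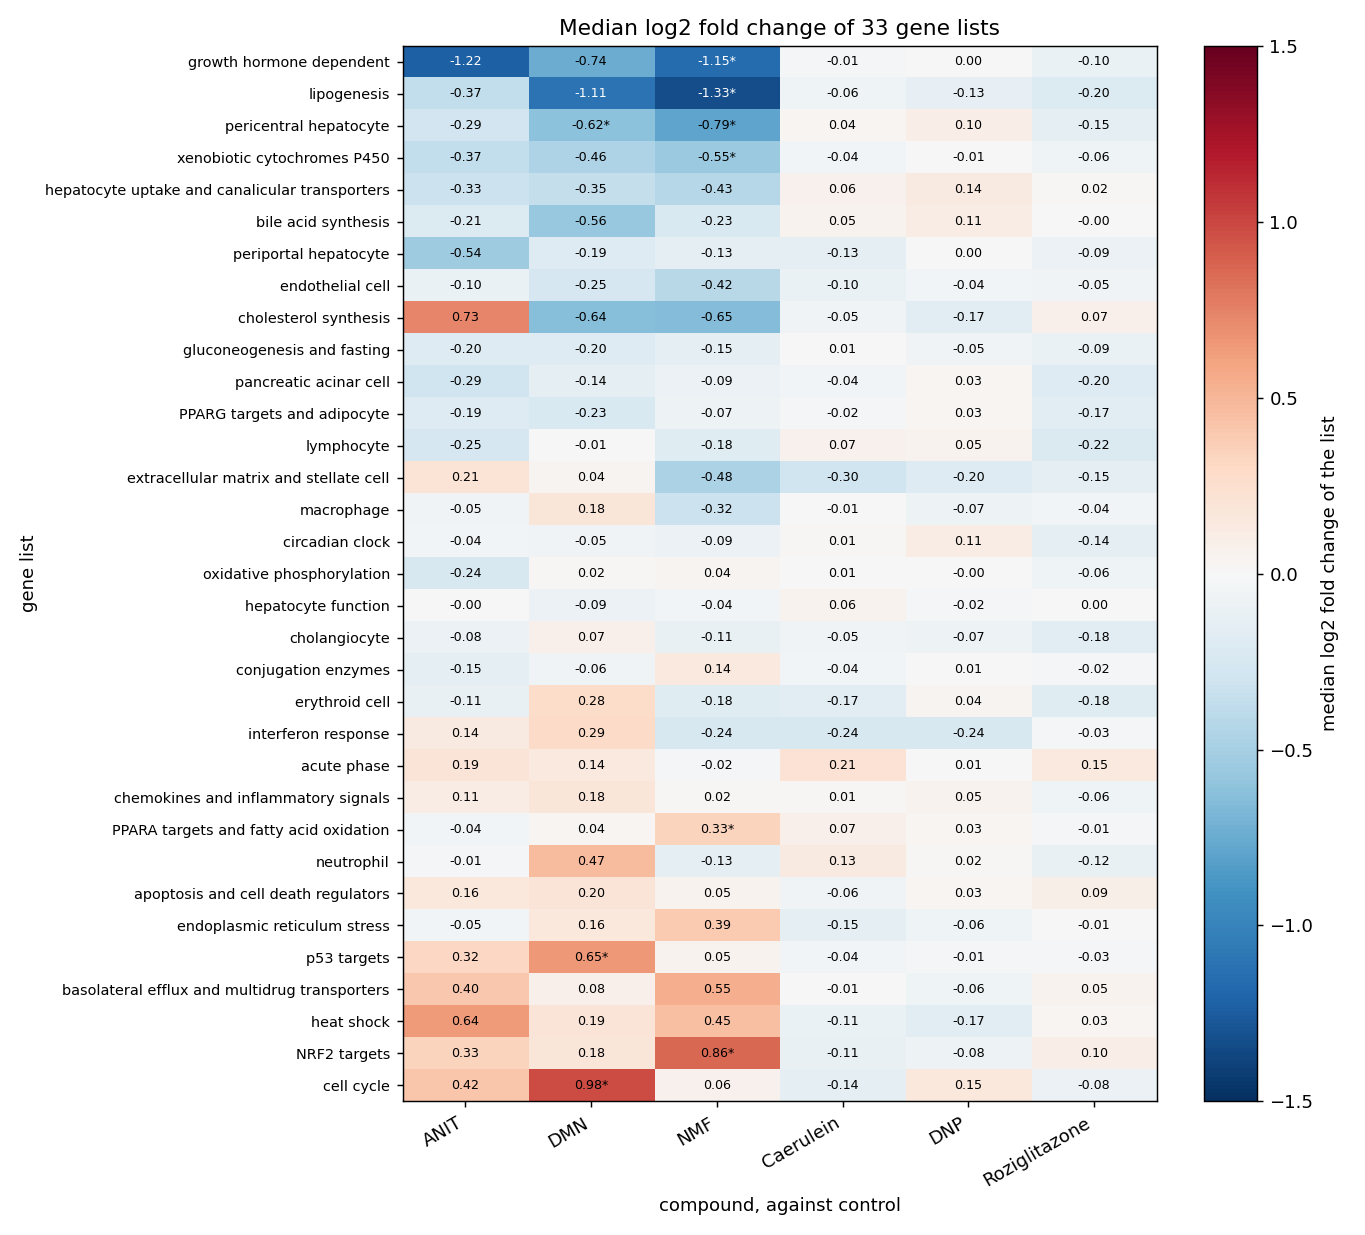
Median log2 fold change against the controls of each of the 33 gene lists (vertical) for the 6 compounds (horizontal), with an asterisk where the adjusted p with an estimated correlation is under 0.05. Cell cycle has its highest median in DMN (0.98), NRF2 targets in NMF (0.86) and cholesterol synthesis in ANIT (0.73).

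Lists that passed in none of the 3 toxicants also had called members. Hepatocyte uptake and canalicular transporters had 5 of 12 lower and 1 higher in ANIT, 1 lower in DMN, and 4 lower and 1 higher in NMF. Cholangiocyte genes had 3 of 13 higher and 1 lower in ANIT (median −0.08, mean 0.18, test upward), 2 higher and 1 lower in DMN, and 2 higher in NMF (median −0.11, mean 0.07, test upward). PPARG targets had 2 of 20 higher and 5 lower in ANIT, and circadian clock genes 1 of 17 higher and 3 lower. Hepatocyte function genes had 2 of 23 higher and 2 lower in ANIT, 1 and 3 in DMN, and 5 lower in NMF. Gluconeogenesis had 1 of 18 higher and 2 lower in ANIT (median −0.20, mean −0.03, test upward) and 2 lower in DMN. Erythroid genes had 2 of 8 lower in NMF, and the interferon response 1 of 26 higher in ANIT, none in DMN and 2 lower in NMF. In ANIT the test also pointed up with a negative median for macrophages (median −0.05, mean 0.11), erythroid genes (−0.11, 0.07), endoplasmic reticulum stress (−0.05, 0.07) and PPARA targets (−0.04, 0.01), in DMN for lymphocytes (−0.01, 0.01), and in NMF the chemokine list had a median of 0.02, a mean of −0.04 and a test upward. In DMN the PPARA list had a median of 0.04, a mean of −0.03 and a test upward.

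Caerulein, an analogue of cholecystokinin that inflames the pancreas, changed no gene past the threshold. limma called 0 genes at a lowest adjusted p of 0.236, with 541 genes at an unadjusted p under 0.05; a per-gene test with unequal variances also called 0, limma with array weights called 5, and leaving out Caerulein 3 gave 1 call. Acute phase genes passed at list level (median 0.21, camera adjusted p = 1.04e-10; adjusted p = 0.0718 with an estimated correlation; 0 of 24 members called, 2 higher adjusted over the list alone). Lcn2 was at 10.60 ± 2.25 (SD, n = 5) against 8.01 ± 0.96 (SD, n = 9), with adjusted p = 0.994. Extracellular matrix and stellate cell genes fell as a list (median −0.30, camera adjusted p = 2.3e-04; adjusted p = 0.133 with an estimated correlation), with Col1a1 at −1.04 ± 0.33. Pancreatic acinar genes did not pass (median −0.04; adjusted p = 0.778). In all, 5 lists passed, 3 without control 2 and 8 without Caerulein 5. The remaining 3 passed neither with an estimated correlation nor with fry, had no member called over all genes, and lost their camera call without single arrays. Pericentral hepatocyte genes were higher (median 0.04; adjusted p = 0.436 with an estimated correlation; 1 higher adjusted over the list alone), lost without Caerulein 2, 3 or 4 or control 2 or 5 (adjusted p up to 0.141). Cell cycle genes were lower (median −0.14; adjusted p = 0.757 with an estimated correlation), lost without Caerulein 2 or 4 or control 2 or 3 (up to 0.103). The interferon response was lower (median −0.24; adjusted p = 0.758 with an estimated correlation), lost without Caerulein 1, 4 or 5 or control 2 or 7 (up to 0.392).

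DNP, which uncouples respiration from ATP synthesis, changed no gene past the threshold in limma either, with 199 genes at an unadjusted p under 0.05; the per-gene test and array weights called 0 each. Oxidative phosphorylation genes had a median of 0.00 and did not pass (camera adjusted p = 0.164). At list level 8 passed, none with fry or with an estimated correlation. The interferon response was lower (median −0.24, camera adjusted p = 3.5e-09; adjusted p = 0.289 with an estimated correlation), as were extracellular matrix and stellate cell genes (median −0.20; adjusted p = 0.0600 with an estimated correlation), heat shock (−0.17; 0.264), cholesterol synthesis (−0.17; 0.519, lost without DNP 1 at camera adjusted p = 0.0581), lipogenesis (−0.13; 0.460), endoplasmic reticulum stress (−0.06; 0.263) and NRF2 targets (−0.08; 0.499). Cell cycle genes were higher (median 0.15; adjusted p = 0.709 with an estimated correlation). Leaving out DNP 1 also ended the camera calls of lipogenesis (adjusted p = 0.258), endoplasmic reticulum stress (0.0961), cell cycle (0.176) and NRF2 targets (0.220). Lipogenesis was lost as well without DNP 5 (0.0529) or control 3 (0.0826), cell cycle without DNP 2 (0.108), and NRF2 targets without DNP 2 (0.244), DNP 4 (0.0613) or control 2, 3, 6, 7 or 8 (0.0516 to 0.0931). The clock genes Nr1d1 (1.23 ± 0.34) and Nr1d2 (1.19 ± 0.40) were higher adjusted over the circadian list alone and were not called over all genes.

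Roziglitazone, an activator of PPARG, changed no gene past the threshold in limma (lowest adjusted p 0.560; 1044 genes at an unadjusted p under 0.05; 0 by the per-gene test, 9 with array weights). PPARG targets and adipocyte genes did not pass (0 of 20 called; median −0.17, camera adjusted p = 0.157), and neither did PPARA targets (median −0.01). Cd36 was at 0.67 ± 0.70 and Plin1 at −0.49 ± 0.16, neither called. Acute phase genes were higher as a list (median 0.15, camera adjusted p = 1.3e-04; adjusted p = 0.357 with an estimated correlation), a call lost without Roziglitazone 3 (adjusted p = 0.0590), and apoptosis genes were higher (median 0.09; adjusted p = 0.157 with an estimated correlation). Lymphocyte genes were lower (median −0.22; adjusted p = 0.520 with an estimated correlation), lost without Roziglitazone 1 (0.0558) or 2 (0.0931). Lipogenesis was lower (median −0.20; adjusted p = 0.613 with an estimated correlation), lost without Roziglitazone 1, 2, 3 or 5 or control 2, 3, 7 or 8 (0.0562 to 0.179). The array labelled Roziglitazone 2 had growth hormone dependent genes at −1.13, basolateral efflux transporters at 1.25 and cholesterol synthesis at 0.92, close to the ANIT arrays, and the other 4 Roziglitazone arrays had growth hormone dependent genes from −0.18 to 0.29. Leaving out the 3 doubted arrays, limma again called 0 genes.

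The 3 liver toxicants were compared with the other 3 compounds, which sets treated animals against treated animals. A difference here can come from either side. Stac3 fell 18.5-fold (−4.21 ± 0.41, adjusted p = 4.36e-09), Akr1c1 13.5-fold, Fmo1 10.4-fold and Oat 5.28-fold (−2.40 ± 0.20, adjusted p = 1.12e-10). Akr1b7, an aldose reductase gene, rose 12.5-fold (3.64 ± 0.56, adjusted p = 9.25e-06), Rnd1 6.61-fold (2.72 ± 0.30, adjusted p = 2.29e-08), the stress factor gene Atf3 5.43-fold and the cell cycle inhibitor gene Cdkn1a 2.66-fold. Akr1b7, Rnd1, Atf3, Stac3, Akr1c1, Fmo1 and Oat lay on the called side of the mean of the other compounds in all 15 toxicant arrays, and Cdkn1a in 14 of 15. For Akr1b7, Atf3 and Cdkn1a the control means of 7.29, 6.42 and 9.89 lay above the means of all 3 other compounds, and against control Akr1b7 was called in NMF, Atf3 in ANIT and DMN, and Cdkn1a in DMN alone. Of the 22 genes named for this contrast, 20 of them chosen because the compound means do not overlap, 10 did so in all 15, and for 0 of the 22 did all 15 toxicant arrays lie past every array of the other compounds (2 of 15 for Rnd1, 12 of 15 for Akr1c1). The arrays of the other compounds held the doubted array labelled Roziglitazone 2. In it Rnd1 was at 9.26 (other Roziglitazone arrays 4.73 to 5.49) and Stac3 at 6.0 (10.71 to 11.31). These counts were not made without that array.

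In this contrast limma called 2695 genes, 1375 higher and 1320 lower (2176 and 656 of 2832 with arrays centred on their median). The 3 toxicant means and the 3 other means did not overlap in 3386 genes, 2006 of them called, where chance gives 1422. Without the 3 doubted arrays 3191 genes were called, 2512 of them among the 2695; array weights gave 4491, leaving out Caerulein from the other compounds gave 1770, and leaving out DNP gave 1611. Of 18 lists past the camera threshold, 5 kept an adjusted p under 0.05 with an estimated correlation. These were pericentral hepatocytes (10 of 14 lower, median −0.65; adjusted p = 0.0101), NRF2 targets (15 of 23 higher, 1 lower, median 0.52; 0.0107), p53 targets (10 of 19 higher, 3 lower, median 0.32; 0.0242), growth hormone dependent genes (13 of 17 lower, median −1.02; 0.0242) and xenobiotic cytochromes P450 (16 of 28 lower, median −0.39; 0.0307). Adjusted over the list alone these counts were 10, 17 and 1, 11 and 3, 16, and 17 lower with 1 higher. The other 13 did not pass with an estimated correlation, and all of them but the interferon response passed with fry.

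Among those 13 lists of the class contrast, heat shock had 9 of 15 higher (10 adjusted over the list alone, adjusted p = 0.0718 with an estimated correlation), endoplasmic reticulum stress 10 of 23 higher and 1 lower (12 and 2; 0.0735), cell cycle 21 of 37 higher (25; 0.133) and lipogenesis 12 of 21 lower (13; 0.133). Apoptosis and cell death regulators had 10 of 37 higher and 2 lower (13 and 3; 0.161), basolateral efflux transporters 3 of 6 higher (3 higher and 1 lower; 0.169), bile acid synthesis 7 of 13 lower (7; 0.182) and periportal hepatocytes 7 of 14 lower and 1 higher (7 and 1; 0.296). The camera calls of 5 lists were lost without single arrays. Cholangiocyte genes (3 of 13 higher, 3 adjusted over the list alone; 0.357 with an estimated correlation) lost theirs without ANIT 1, Caerulein 2, DMN 2 or 5, DNP 4 or 5, NMF 1 or 5 or Roziglitazone 2 (adjusted p from 0.0509 to 0.0857). Endothelial genes (3 of 12 lower, 5 adjusted over the list alone; 0.520) lost it without ANIT 3, Caerulein 2, DNP 1, NMF 2 or 5 or Roziglitazone 1 or 2 (0.0528 to 0.0703). The same held for hepatocyte uptake and canalicular transporters (6 of 12 lower and 1 higher, 7 and 2 adjusted over the list alone; 0.483) without DMN 5, DNP 4, NMF 5 or Roziglitazone 4 (0.0513 to 0.0865). Pancreatic acinar genes (4 of 13 lower, 4 adjusted over the list alone; 0.520) lost it without Caerulein 5 (0.0509) or NMF 4 (0.0516). The interferon response (4 of 26 higher, 3 adjusted over the list alone; 0.757) lost it without ANIT 5 (0.147), DMN 3 (0.168) or NMF 4 (0.0764), and had adjusted p = 0.398 with fry.

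Genes called the same way in all 3 liver toxicants were counted next, with the caution that the compounds share their controls. Stac3 fell 39.6-fold, 20.5-fold and 28.3-fold in ANIT, DMN and NMF, Oat 6.65-fold, 4.90-fold and 5.82-fold, and Pklr 9.31-fold, 4.00-fold and 7.56-fold. Rnd1 rose 18.2-fold, 6.24-fold and 3.87-fold, the antioxidant gene Srxn1 6.24-fold, 3.62-fold and 3.53-fold, the retinal dehydrogenase gene Aldh1a1 3.36-fold, 3.63-fold and 3.24-fold, and Gpnmb 3.76-fold, 9.28-fold and 5.08-fold. In limma 293 genes were called the same way in all 3, 129 higher and 164 lower, of 3519 called in at least 1. Independence would give 2.63 higher and 1.94 lower. The per-gene test gave 28 shared genes and array weights 635. Another 27 genes were called in opposite ways in 2 toxicants. With 3 control arrays of its own for each compound, 32 genes were shared (12 higher, 20 lower), from 980, 308 and 422 calls. Without the 3 doubted arrays 346 genes were shared. With each array centred on its median, 188 shared genes were higher and 84 lower.

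Across genes, which are not independent replicates, the fold changes of ANIT and DMN correlated at r = 0.638 (covariance 0.139), ANIT and NMF at 0.496 (0.0988), and DMN and NMF at 0.513 (0.0913). Simulations with shared controls and no planted effect gave a mean r of 0.348, from −0.170 to 0.782, with a mean covariance of 0.0209 and a highest of 0.0840. They drew on the deviations of all arrays from their labelled group means, the doubted arrays and those low in GAPDH 5′ signal included. Their spread therefore cannot be put down to shared controls alone. With the controls split into 4 and 5 so that none was shared, r was 0.423, 0.293 and 0.267 and the covariances 0.107, 0.0651 and 0.0559. Several other pairs of compounds fell below 0 with this single random split, so 0 is not a firm reference for it. ANIT and Roziglitazone correlated at 0.555 with shared controls, 0.225 with split ones, and 0.215 without the array labelled Roziglitazone 2. Without the array labelled ANIT 3, r for ANIT and DMN was 0.508 with shared controls, the lowest on leaving out any 1 array. The value of 0.423 with split controls still held that array.

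ANIT and DMN, an agent of the bile ducts and an agent of the hepatocytes, were compared directly, with counts of list members and no test of lists. Of the cholesterol synthesis genes 15 of 22 were higher in ANIT (18 adjusted over the list alone, median 1.39), among them Cyp51 by 4.43-fold (2.15 ± 0.36, adjusted p = 0.00386). Abcb4 was 3.61-fold higher (1.85 ± 0.35, adjusted p = 0.00513) and Gpx2 7.64-fold. Serpina6 was 8.82-fold lower in ANIT (−3.14 ± 0.64, adjusted p = 0.00668) and the phospholipase gene Plaat3 2.71-fold lower. Each of these 5 genes differed in all 5 ANIT arrays from the DMN mean, as did 3 of the 6 genes named for this pair without the condition on overlap.

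This comparison called 359 genes, 207 higher and 152 lower in ANIT (149 and 76 of 225 with arrays centred on their median, 164 and 169 of 333 with quantile normalization once more), and its count rested on single arrays. It was 1064 without the array labelled ANIT 3, 65 without ANIT 5, 79 without ANIT 4, 98 without ANIT 2, 136 without ANIT 1 and 218 without DMN 4. Leaving out all 3 doubted arrays, it was 1116, 352 of them among the 359. A fit to these 2 groups alone called 0 genes, as did the per-gene test, and array weights 1769, with 2327 genes at an unadjusted p under 0.05 in limma over all groups. Cell cycle genes had 4 of 37 lower in ANIT and 1 higher, and 14 and 1 adjusted over the list alone. The groups did not overlap in 302 genes, 87 of them called, where chance gives 113.

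ANIT and NMF were compared next, again with no test of lists. Lcn2 was 38.6-fold higher in ANIT (5.27 ± 1.02, adjusted p = 0.00103), Sqle 8.81-fold, Idi1 9.20-fold and Cyp1a2 6.94-fold (2.80 ± 0.15, adjusted p = 3.6e-16). Akr1b8 was 47.5-fold lower (−5.57 ± 0.45, adjusted p = 5.04e-11), Gstp1 13.2-fold lower and Abcg5 7.19-fold lower. Each held in all 5 ANIT arrays against the NMF mean, as did 3 of the 4 genes named for this pair without the condition on overlap. In limma 940 genes differed, 534 higher and 406 lower in ANIT (488 and 312 with arrays centred on their median, but 457 and 532 with quantile normalization once more), and 1331 without the 3 doubted arrays (874 shared); the per-gene test called 181 and array weights 2934. The count was 485 without NMF 5, 495 without ANIT 5, 622 without NMF 2 and 1137 at most, without ANIT 3. Cholesterol synthesis had 15 of 22 higher (20 adjusted over the list alone), acute phase 8 of 24 higher (10 higher and 1 lower adjusted over the list alone), lipogenesis 7 of 21 higher (10 adjusted over the list alone) and extracellular matrix 7 of 26 higher (13 adjusted over the list alone). NRF2 targets had 8 of 23 lower (9 lower and 2 higher adjusted over the list alone), conjugation enzymes 8 of 28 lower (10 and 1 adjusted over the list alone) and PPARA targets 8 of 31 lower and 1 higher (12 and 1 adjusted over the list alone).

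DMN and NMF were compared in the same way. Adam8 was 20.3-fold higher in DMN (4.34 ± 0.52, adjusted p = 8.6e-07), Ccnb2 10.8-fold, Ube2c 10.2-fold, and Cdkn1a 3.40-fold (1.77 ± 0.44, adjusted p = 0.0107). Akr1b8 was 22.1-fold lower (−4.46 ± 0.45, adjusted p = 1.24e-08), Abcc3 15.6-fold and Gpx2 14.7-fold. The 3 genes named for this pair without the condition on overlap differed in all 5 DMN arrays from the NMF mean. In limma 662 genes differed, 426 higher and 236 lower in DMN, and 1028 without the 3 doubted arrays (630 shared); a fit to these groups alone called 186, the per-gene test 8 and array weights 1859. Cell cycle had 19 of 37 higher (27 adjusted over the list alone), p53 targets 5 of 19 (7), macrophages 5 of 17 (8), neutrophils 3 of 13 (5) and erythroid genes 3 of 8 (3), the heme synthesis gene Alas2 by 8.67-fold. NRF2 targets had 10 of 23 lower (11 lower and 1 higher adjusted over the list alone) and conjugation enzymes 7 of 28 (10).

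The 5′ end of GAPDH was dim on 6 arrays, those labelled DMN 3, DNP 1, NMF 3, Roziglitazone 1, control 4 and control 5. Its log2 signal was 6.34 to 7.42 on these and 10.49 to 12.93 on the other 33, and at the 3′ end 8.09 to 13.06 against 12.66 to 13.27. Without these 6 arrays the calls were 3632 in ANIT, 1373 in DMN and 1362 in NMF, and 360 genes were shared by all 3.

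**Figure D3:**
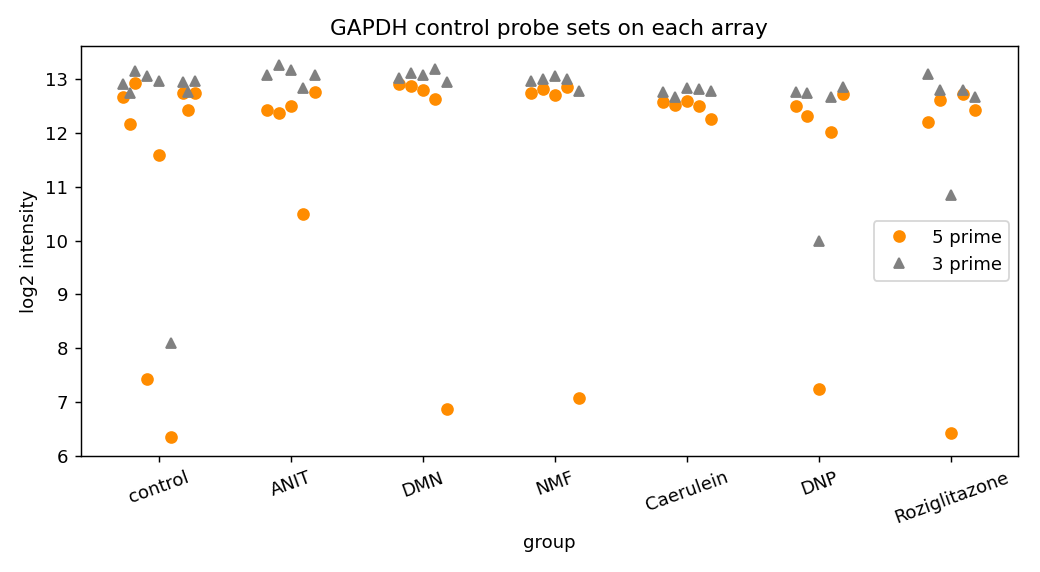
Log2 signal of the GAPDH 5′ and 3′ control probe sets on each of the 39 arrays by group. The 6 dim arrays lie from 6.34 to 7.42 at the 5′ end and the other 33 from 10.49 to 12.93.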

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

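The tests of the labels, of a mixed sample, of a general injury response and of beta-actin signal were chosen after the result was seen; those of a weaker ANIT response, the hybridization spikes and the poly-A spikes were set before. For the named genes and the GAPDH 5′ signal, 385 groups were searched for 1 array far from the rest, by the gap to its neighbour as a share of the group's range at the 5% level. Such an array was found in 63 groups, 57 of them genes, where chance gives about 1 in 20 groups. Of the 63, the array labelled ANIT 3 made 18, DMN 2 made 11, Roziglitazone 2 made 7 and control 5 made 6.

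The array labelled ANIT 3 lay below the other 4 ANIT arrays in log2 intensity for genes of cholesterol synthesis, Idi1 at 9.11 (others 11.91 to 12.61), Sqle at 9.14 (others 11.45 to 11.76), Acat2 at 7.59 and Cyp51 at 11.01, and for Acss2 at 8.22, Abcc3 at 7.15, Gpx2 at 6.0, Gstm3 at 7.80, Neurl3 at 9.01, Ccnd1 at 10.05 and Slc13a3 at 6.92. It lay above them for Ccna2 at 8.77 (others 5.00 to 6.08), Ccnb2 at 10.35 (others 5.78 to 6.36), Cdkn1a at 11.91, Akr1b7 at 11.11, Serpina6 at 10.16, Pklr at 8.96 and Abcg5 at 7.85. Over 1116 genes that set ANIT and DMN apart, its position between the other ANIT arrays (0) and the DMN arrays (1) was 0.930, inside the DMN range of 0.889 to 1.01 and outside the ANIT range of −0.0869 to 0.122. A weaker response to ANIT in 1 animal is excluded: over 1123 genes called in DMN and not in ANIT its position between control (0) and DMN (1) was 0.984, where the other ANIT arrays lay from 0.103 to 0.218. A candidate explanation that stays open is a DMN sample under a wrong label.

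The array labelled Roziglitazone 2 lay above the other 4 of its group for Rnd1 at 9.26 (others 4.73 to 5.49) and Gstm3 at 11.84, and below them for Stac3 at 6.0 (others 10.71 to 11.31), Fmo1 at 7.53, Car3 at 9.13, Oat at 9.54 and Cyp2c11 at 10.95. Its position between Roziglitazone (0) and ANIT (1) was 0.930 over 1625 genes, where ANIT arrays lay from 0.921 to 1.08 and other Roziglitazone arrays from 0.00612 to 0.0942. Its nearest array was ANIT 2, with r = 0.992 across genes. A mix with at least 50% of its RNA from a Roziglitazone sample is excluded, since 42 genes at least 4-fold lower in ANIT lay at a median of −2.44 (quartiles −3.07 and −1.80) in it. A general response to liver injury is excluded by its position of 0.902 between DMN with NMF (0) and ANIT (1) over 421 genes, where ANIT arrays lay from 0.886 to 1.18 and DMN and NMF arrays from −0.142 to 0.121. An ANIT sample under a wrong label stays a candidate explanation.

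The array labelled DMN 2 lay above the other 4 DMN arrays for Stac3 at 9.79 (others 5.38 to 6.34), Obp3 at 11.83, Nrep at 11.07 and Fabp7 at 12.37. It lay below them for Lcn2 at 8.0 (others 12.49 to 13.19), Lyz2 at 11.61, Gpnmb at 9.34, Ube2c at 8.25, Lama5 at 7.49, Tubb6 at 9.07 and Cdkn1a at 10.30. In other genes it lay far from the other 4 Roziglitazone arrays on the DMN side, as in Mybl1 at 7.16 (Roziglitazone 3.87 to 4.27), Adam8 at 8.51 (4.80 to 6.22) and Oat at 10.35 (12.18 to 12.60). An exchange of 3 labels in a ring, with the Roziglitazone sample under the DMN 2 label, was tested on p53 targets. Their mean level in the array labelled DMN 2 was 0.339. This level lay outside the bound given below, which argues against the exchange and does not exclude it. The other 4 Roziglitazone arrays lay from −0.111 to −0.106, and all 23 arrays of control, Caerulein, DNP and Roziglitazone from −0.180 to 0.119. With the spread pooled within these groups, the 95% bound for a further Roziglitazone array, corrected for 33 lists, was 0.234, and the other DMN arrays lay from 0.674 to 0.845. This list was taken up after the levels of all 33 had been seen, and it was the 1 list of 33 outside such a bound; cell cycle at 0.43 and pericentral genes at −0.18 were inside. Its position between Roziglitazone (0) and DMN (1) over 1288 genes, 0.246, did not decide. It lay below the DMN range of 0.798 to 1.08 and above the range of −0.0750 to 0.156 of the other 4 Roziglitazone arrays, whose own spread allows up to 0.419 (95% prediction). A count of genes decided little either: in 540 of the 1288 it lay past the other 4 Roziglitazone arrays on the DMN side, where a Roziglitazone array lay past the other 3 in up to 507. Its nearest array was Roziglitazone 5, with r = 0.975 across genes. Its deviation from the mean of all other arrays, a measure unlike that r, correlated best with the deviation of Roziglitazone, at 0.120. That Roziglitazone mean included the array labelled Roziglitazone 2. A weak response of this animal to DMN and a mix of samples stay open, and the exchange of labels is not excluded. The report's counts with and without the 3 arrays show what they move, and no array was given another label.

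The 5′ signal of GAPDH was low on DMN 3 at 6.87, DNP 1 at 7.24, NMF 3 at 7.08 and Roziglitazone 1 at 6.42, each far from the rest of its group; among the controls, arrays 4 and 5 were low together. Smaller gaps set apart ANIT 5 at 10.49 (others 12.38 to 12.77) and Caerulein 3 at 12.26 (others 12.51 to 12.60). Degraded RNA or incomplete cDNA stays open as an explanation of the 6 low arrays. The highest beta-actin 5′ signal among them was 7.26, and the other 33 arrays lay from 9.24 to 12.7. For beta-actin the loss was not confined to the 5′ end, since beta-actin 3′ was 8.37 to 9.66 against 11.56 to 13.20, and the 3′ minus 5′ difference of 1.29 to 2.80 lay inside the range of 0.297 to 2.89 of the other 33. For GAPDH, whose 5′ signal picked these arrays, that difference was 1.75 to 6.07 against 0.0710 to 2.33. The 6 arrays were not alike in this. GAPDH 3′ was 12.94, 12.78 and 13.06 on DMN 3, NMF 3 and control 4, inside the range of the other 33. It was 8.09, 9.99 and 10.84 on control 5, DNP 1 and Roziglitazone 1, below that range. Weaker hybridization or scanning of whole arrays was not settled. The hybridization spikes differed by a median of −0.146 (−0.939 to 0.648), which lay above the limit set before. The values had already been brought to a shared scale, which can remove a loss common to a whole array. A fault of labelling and one of the liver RNA cannot be told apart, because the poly-A spikes that would decide it (difference −0.197, range −0.347 to −0.0470) had mean log2 signals of 3.47 to 4.80, near background. The low arrays spread over 5 groups, with 2 among the controls and none in ANIT or Caerulein, and no biological explanation was tested. Over all 39 arrays the GAPDH 5′ signal went with the main axes of variance of the genes (principal components). Its absolute r was 0.705 with component 1 (21.9% of the variance) and 0.587 with component 2 (17.0%).

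Single arrays stood apart in further genes. Control 5 was high for Btg3 at 7.89, Oat at 12.68, Acss2 at 11.27, Cyp2j3 at 11.77 and Acot2 at 10.39, and low for Serpina6 at 9.81 (others 12.22 and above). Control 1 was high for Srxn1 at 9.25 and Cyp1a1 at 8.30 and low for Kdr at 9.09. Control 4 was high for Apaf1 at 7.42 and control 2 for Akr1b8 at 7.53. DMN 5 was low for Igfals at 7.36 and Fas at 7.26 and high for Akr1b8 at 8.90, and DMN 1 was high for Pkdcc at 9.32. NMF 4 was low for Cyp8b1 at 7.10 (others 10.04 to 10.72) and high for Mybl1 at 5.66. DNP 1 was high for Abcc3 at 6.58 and low for Serpina6 at 10.78. Caerulein 2 was low for Dhrs7l1 at 8.49 (others 11.19 to 12.09) and Car3 at 13.04.

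Signal also changed in data that the comparisons do not use. Among the 9780 probe sets with no listed gene, limma called 435 in ANIT (134 higher, 301 lower), 105 in DMN (43 higher, 62 lower) and 83 in NMF (29 higher, 54 lower), and 0 in each of the other 3 compounds, where 241, 106 and 646 had an unadjusted p under 0.05 in Caerulein, DNP and Roziglitazone.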

How the results depend on the processing

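Planned before the data were examined were all alternatives except those on the 6 arrays low in GAPDH 5′ signal and the 3 arrays labelled ANIT 3, DMN 2 and Roziglitazone 2, which were chosen after the result was seen. No call of a named gene or list reversed under any alternative run. With split controls 9 of 15 correlations of fold changes turned from positive to negative (values below), and those of ANIT with Caerulein and with DNP, 0.0233 and 0.00990, also did so without single arrays (lowest −0.0368 and −0.0354). Which direction held more genes turned under some alternative in every comparison with calls except DMN against NMF (4 and 4 by the per-gene test): with quantile normalization once more ANIT had 1073 higher and 1009 lower, ANIT against DMN 164 and 169, and ANIT against NMF 457 and 532, and with arrays centred on their median the shared genes were 188 and 84. Counts stayed within 1.5 times the first value with the mean of probe sets, all probe sets, both filters on dim genes, a further quantile normalization, and a trended and robust prior. Of 199 named gene results, 18 lost their call without some 1 array, and none reversed. Calls were lost for 21 of them in a fit to the named groups only, 13 with the replicate block, 4 without the 6 low arrays, 3 with arrays centred on their median, 2 with the mean of probe sets, 2 without the 3 arrays and 1 with array weights.

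The replicate number as a block left 1695 genes in ANIT, 1182 in DMN, 926 in NMF, 2867 in the class contrast, 311, 998 and 681 in the pairs ANIT and DMN, ANIT and NMF, and DMN and NMF, 218 shared, and 0 in the other 3. Its lists were 13, 4, 14, 5, 13, 3 and 16 for ANIT, Caerulein, DMN, DNP, NMF, Roziglitazone and the class, the 5 of DNP down from 8. In ANIT the block ended the camera calls of basolateral efflux transporters (adjusted p = 0.0797), lymphocytes (0.0816), pericentral hepatocytes (0.200) and oxidative phosphorylation (0.214). Of 105 pairs of arrays with 1 number, 58 had r above 0.1 in their deviations from the group means. Of 30 treated arrays, each set against all 9 controls, 5 were closest to the control of their number. Unlike-numbered controls were thus a reference for the 5, but unlike-numbered pairs were not counted as one for the 58. These values do not settle whether the numbers pair samples.

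Array weights raised ANIT to 4839, Caerulein to 5, DMN to 3468, NMF to 1900, Roziglitazone to 9, the class contrast to 4491, ANIT against DMN to 1769, ANIT against NMF to 2934, DMN against NMF to 1859 and shared genes to 635; the cause was not tested. A fit to the named groups only gave 859 for DMN, 0 for ANIT against DMN and 186 for DMN against NMF, with fewer arrays behind the spread. The per-gene test with unequal variances, which pools no spread, gave 219 for DMN, 0, 181 and 8 for ANIT against DMN, ANIT against NMF and DMN against NMF, and 28 shared, and was not run for the class contrast. Centring arrays on their median gave 225 for ANIT against DMN, the cause not tested. Leaving out Caerulein or DNP from the class contrast gave 1770 or 1611, with fewer arrays.

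Estimated correlations left 0 lists in ANIT, 0 in Caerulein, 3 in DMN, 0 in DNP, 6 in NMF, 0 in Roziglitazone and 5 in the class contrast, the cause not tested. fry left 2 in Caerulein, 0 in DNP and 1 in Roziglitazone, asking another question.

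Without the 6 low arrays ANIT had 3632 genes, ANIT against DMN 587 and ANIT against NMF 1808, and with these arrays as a block 3646, 978 and 2178, with 8 lists in Caerulein. Without these 3 arrays, ANIT against DMN had 1116 and DMN against NMF 1028. Without both sets NMF had 1633, ANIT against DMN 1477, ANIT against NMF 2353, DMN against NMF 1042, and 470 were shared. The cause of these higher counts was not tested.

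Leaving out 1 array moved ANIT against DMN from 65 (without ANIT 5) to 1064 (without ANIT 3), with 79, 98, 136 and 218 without ANIT 4, ANIT 2, ANIT 1 and DMN 4. ANIT against NMF ran from 485 (without NMF 5) to 1137 (without ANIT 3), with 495 without ANIT 5 and 622 without NMF 2. Caerulein had 0 to 1 genes (1 without Caerulein 3) and 3 to 8 lists. Ranges elsewhere were 1693 to 2752 for ANIT, 1007 to 1817 for DMN, 720 to 1133 for NMF, 456 to 928 for DMN against NMF, 2255 to 3066 for the class and 207 to 326 shared; the causes were not tested.

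Splitting the controls, which removes the shared ones, left 32 shared genes with 3 controls each and these correlations of fold changes with 4 and 5: ANIT and Caerulein −0.144, ANIT and DMN 0.423, ANIT and DNP −0.233, ANIT and NMF 0.293, Caerulein and DMN −0.134, Caerulein and DNP −0.229, Caerulein and NMF −0.129, Caerulein and Roziglitazone −0.152, DMN and DNP −0.210, DMN and NMF 0.267, DMN and Roziglitazone 0.131, DNP and NMF −0.248, DNP and Roziglitazone −0.193, NMF and Roziglitazone 0.0349. Signal near background limits small folds in dim genes.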

Other observations

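The tests of the 3 scores and of other groupings of the samples below were planned before the result was seen. The placement of single arrays was looked at after the result was seen. The mean level of the cholesterol synthesis list against the controls was 1.05 to 1.47 in the ANIT arrays other than ANIT 3, −0.60 in ANIT 3 and −0.08 to −1.12 in the 5 DMN arrays. Cell cycle lay at 0.90 to 1.72 in the DMN arrays other than DMN 2. Endothelial genes lay at −0.84 in the array labelled ANIT 3, and p53 targets at 0.96.

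A response shared by the liver toxicants was tested by choosing genes on 2 toxicants and scoring the third. The score was the mean log2 level of the genes called higher in both minus that of the genes called lower in both, compared between the third toxicant (n = 5) and the other 3 compounds (n = 15) by one-sided exact permutation tests over 15504 splits. For ANIT, with 188 genes higher and 249 lower in DMN and NMF, the score was 1.30 ± 0.31 (SD) against −0.07 ± 0.39 (exact p = 1.93e-04, adjusted 5.8e-04). For DMN, with 215 and 255 genes, it was 0.71 ± 0.44 against −0.53 ± 0.51 (exact p = 7.09e-04, adjusted 0.00106). For NMF, with 371 and 354 genes, it was 0.02 ± 0.32 against −0.94 ± 0.47 (exact p = 0.00148, adjusted 0.00148). The control means were −0.34, −0.79 and −1.19. In ANIT, DMN and NMF, 3, 0 and 0 of 5 arrays exceeded every array of the other compounds, and 5, 5 and 5 when the array labelled Roziglitazone 2 was left aside. These values are consistent with a response that ANIT, DMN and NMF share at 48 h, though the array labelled ANIT 3 sat with DMN, so the choice of genes and the scored arrays were not fully apart for DMN and ANIT.

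For the counts of genes, 100 splits of the same arrays, the real one included, were fitted. Only the real split reached its own count for ANIT (real 2344, highest other 527), DMN (1478, 1105) and NMF (1063, 82). The same held for ANIT against NMF (940, 412) and the genes shared by the toxicants (293, 0). For the shared genes the labels were drawn over ANIT, DMN, NMF and control together, which breaks up every compound effect. That count therefore cannot tell sharing from separate effects of the compounds. For DMN against NMF 3 splits were as large (real 662, highest other 1812), under the limit of 5 set per test. That limit was not corrected over the tests. Chance cannot be excluded for ANIT against DMN (5 splits, real 359, highest other 984). For Caerulein, DNP and Roziglitazone the real count is 0, so all 100 splits are as large whatever the data, and the splits decide nothing (highest others 1, 503 and 1429). Splits with several times the real count, as for ANIT against DMN and DMN against NMF, point to a structure of the samples; what those splits separate was not tested. For lists, 2 splits were as large in ANIT (real 17, highest other 18), under the same limit, and the median of the other splits was 8. Chance cannot be excluded for Caerulein (49 splits, real 5, highest other 13), DMN (7, 16, 22), DNP (16, 8, 15), NMF (6, 16, 18) and Roziglitazone (85, 4, 13). The medians of their other splits were 4, 9, 5, 8 and 6. The 6 compounds make only 10 splits into 3 and 3, too few for a share under 0.05: the class contrast gave 2695 genes and 18 lists (1 and 2 splits as large), and the highest others were 1644 genes, with Roziglitazone in the place of NMF, and 18 lists.

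The deviation of each array from the mean of all others was also correlated with the deviation of every group mean. Of 39 arrays, 15 correlated best in this way with their own group, and of the 15 toxicant arrays 11 did. The other 4 were ANIT 3 (closest to DMN), DMN 2 (closest to Roziglitazone, at 0.120), and NMF 3 and NMF 4 (closest to ANIT).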
